A study of Mus musculus with 8 samples.

How the data were processed

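Small RNA libraries from mouse cerebellum were analysed from deposited count files, with 8 libraries in 4 groups. Per the series design text, the 6-week libraries pooled RNA from 4 WT and 4 Mecp2-null (KO) males, 1 pool per genotype, and were sequenced together under separate barcodes. The 8-week libraries came from individual males of 2 litters, each with 1 WT and 2 KO animals, per the sample titles and the series design text. Per the labels' protocols, RNA for the 6-week pools was extracted with Trizol, made into libraries with the SREK small RNA kit and size-selected on gels. The 8-week RNA was isolated with the PureLink kit for RNA under 200 bases and made into libraries with the SOLiD total RNA-seq kit, per the labels' protocols. Age, extraction, library kit and pooling therefore changed together, and libraries of both ages were never fitted in the same model.

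The values are whole-number read counts per genomic region inside a microRNA precursor, as deposited by the authors, with no normalization, per the file headers. The aligner, counting tool, genome build and miRBase release were not given in the sources used here. The deposited count files list no region with fewer than 2 reads, so an unlisted microRNA had 0 or 1 read or was not counted. The 6-week count files deposited by the authors list the same 626 regions in both pools, each with at least 2 reads in both, so a microRNA seen in 1 pool alone is not in them. The 8-week files give regions set separately in each library. Many copies of a microRNA at different places held nearly equal counts, as when reads that map to several copies are counted at each; how such reads were counted was not given in the sources used here.

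Regions of the same precursor in different libraries were joined when they overlapped by at least 50% of the shorter region. Copies of the same microRNA whose counts agreed within 10% or 3 reads in every library were taken as the same reads and entered once, with the highest count. The same was done for microRNAs that share a number but not a letter, and for miR-103 with miR-107. Such joint features carry each name, as in miR-106a/miR-106b-5p and miR-103/miR-107-3p. Copies whose counts agreed less closely stayed separate features, so the same microRNA could enter a list more than once. This left 494 features in the 6-week pools and 478 in the 8-week libraries. Regions were named 5p and 3p by their order along the strand where a precursor had a pair of them. Regions listed on both strands, as for miR-1 on chromosome 18 in the 6-week pools, were ordered by rising position. Their arm names may therefore be reversed. A feature without an arm had a single listed region, and members of a family with similar sequences (let-7, miR-29, miR-181, miR-30) may still share reads. Positions are given as in the files, whose build and base numbering were not stated. Their positions differ from those of GRCm38, so GENCODE vM21 was used only to find, by name, the gene in which a microRNA lies; 337 of the 398 compared features were matched by name.

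The 8-week KO libraries were compared with WT in edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with TMM scaling and filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which kept 330 features. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors are those that give the reported F statistic. The difference between litters and the litter by genotype interaction were tested in the same way. MicroRNA lists with at least 3 tested members were compared with limma 3.58.1's camera at a preset correlation of 0.01, with an estimated correlation and with fry. For the 6-week pools, with 1 library per genotype, no test was made. Ratios of TMM-scaled counts were given with exact binomial 95% intervals, which cover counting error only, for the 250 features with at least 100 reads over both pools. A microRNA was counted as apart when its ratio was at least 1.5-fold from 1 and its interval excluded 1. A list's median was set against 10000 random lists of the same size matched on mean expression.

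The libraries held 680604 and 694204 counts in the 6-week pools and from 1494063 to 2372585 in the 8-week libraries after copies were entered once. Reads were not marked by molecular identifiers. The libraries of a group differed by far more than counting error (the smallest chi-square per degree of freedom between any pair of 8-week libraries was 334), so each was kept as a separate replicate. The litter numbers pair the samples because the labels name shared litters. Over the 330 features the litter deviations of WT and of KO correlated weakly (Pearson 0.10, Spearman 0.13). The test was checked on counts simulated from the 8-week means and library sizes, in 10 runs over 330 features. With 40 features changed, it called 8.09% of those changed 2-fold, 49.6% of those changed 4-fold, 90.6% of those changed 8-fold and 0.349% of the unchanged ones. With 200 features changed, the shares were 20.0%, 80.2%, 97.9% and 2.02%.

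The lists, designs, most alternatives and the rule for named microRNAs were fixed before the data were examined. At 8 weeks the text names up to 10 microRNAs in each direction with the smallest p among those past the threshold, or, where too few pass, the 5 with the smallest p in each direction. At 6 weeks it names the 8 highest and the 8 lowest ratios among those counted as apart. At both ages it names the 5 most abundant microRNAs, up to 4 abundant members of each list, and always miR-30a, miR-381, miR-495, miR-206, miR-132, miR-212, miR-137, miR-184, miR-134, miR-199a and miR-146a where counted. Other names were chosen after their values were seen: miR-99a-5p, miR-126-5p, miR-126-3p and miR-331-3p, the microRNAs that differed between litters, and other arms and members of the lists. The lists cover the imprinted Dlk1-Dio3 domain, microRNAs tied to Bdnf, to Mecp2 or to neuronal activity, cell types of the cerebellum, blood and vessels, seed families and X-linked microRNAs. Alternatives were DESeq2 1.42.0 size factors, total-count scaling, other count minimums, DESeq2 and limma-voom as tests, litter as a block, each replicate left out in turn, and each litter on its own. Features of both ages were paired where their regions overlapped by at least 50% of the shorter region, so that a 6-week feature could enter more than once; entering each once was an alternative. No listed region lacked a microRNA name, and 0 columns were left without a sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.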

Results

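Small RNA was sequenced from the cerebellum of male mice lacking Mecp2 (KO), the X-linked gene for a methyl-CpG-binding protein that is mutated in Rett syndrome, and of wild-type males (WT). The question of the series was which microRNAs depend on Mecp2, before or at the onset of symptoms (6 weeks) and in symptomatic animals (8 weeks). The 6-week data were 1 WT and 1 KO library, each a pool of 4 animals, with 680604 and 694204 counts. The 8-week data were 6 individual libraries with 1494063 to 2372585 counts. Litter 1 held WT replicate 1 and KO replicates 1 and 2, and litter 2 held WT replicate 2 and KO replicates 3 and 4. Mecp2 mRNA is not measured in small RNA libraries, so the genotype labels could not be checked against it.

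The most abundant microRNAs of the 8-week cerebellum were miR-29b-3p, miR-181a-5p, miR-451, miR-103-3p and miR-138-5p. MiR-29b-3p took from 17.7% of the counts in WT replicate 2 (95% Wilson interval 17.7% to 17.8%) to 25.8% in WT replicate 1 (25.8% to 25.9%). MiR-451, a red blood cell microRNA, took from 1.94% in KO replicate 1 (1.92% to 1.96%) to 23.6% in WT replicate 2 (23.6% to 23.7%). In the 6-week pools, miR-29c-3p took 14.1% of the WT counts (14.0% to 14.1%) and 9.17% of the KO counts (9.11% to 9.24%). The neuronal miR-124-3p took 6.21% in WT (6.16% to 6.27%) and 10.8% in KO (10.7% to 10.8%). These intervals cover counting error only.

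In the symptomatic cerebellum no microRNA passed the test between KO and WT. The microRNAs that came closest with higher levels in KO were miR-1-5p, miR-101b, miR-874-3p, miR-137-3p and miR-206-3p, and those with lower levels were miR-140-5p, miR-132-5p, miR-365, miR-9-3p from its locus on chromosome 7, and miR-326. MiR-137-3p, a regulator of neuronal maturation, stood at 161 ± 37.6 CPM (reads scaled to library size by TMM) in WT (SD, n = 2) and 312 ± 88.1 in KO (SD, n = 4), a log2 fold change of 0.95 (SE 0.38). MiR-132-5p, from the precursor of the activity-induced miR-132, stood at 233 ± 135 in WT and 91.6 ± 16.2 in KO (log2 fold change −1.35, SE 0.39). MiR-140-5p stood at 73.7 ± 16.9 in WT and 35.5 ± 1.64 in KO (log2 fold change −1.05, SE 0.30).

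For miR-137-3p, miR-206-3p, miR-132-5p, miR-140-5p and miR-326, all 4 KO libraries lay on the same side of both WT libraries. MiR-326 had a log2 fold change of −1.55 (SE 0.50) and miR-365 one of −1.58 (SE 0.51). MiR-874-3p had 1.58 (SE 0.61), with 0.67 in litter 1 and 2.63 in litter 2. These litter values are differences of mean log2 CPM, and edgeR fits to a single litter differ slightly (2.81 in litter 2). The miR-9-3p locus on chromosome 7 had −2.08 (SE 0.68), with 0.24 in litter 1 and −3.19 in litter 2 as differences of mean log2 CPM (−3.11 by the fit to litter 2), and 0.01 without WT replicate 2. The other miR-9-3p feature had −0.86 (SE 0.42). How reads were divided between these features was not given, so a difference particular to the chromosome 7 locus is not shown. Without WT replicate 2 miR-365 had −0.44, miR-132-5p −0.62, miR-326 −0.87 and miR-874-3p 0.98, and without WT replicate 1 miR-874-3p had 2.58. MiR-206-3p, a muscle-enriched microRNA, had 4 and 2 reads in WT and from 8 to 33 in KO. MiR-1-5p was not listed in either WT library and had 16, 2, 2 and 16 reads in the KO libraries. Its arm name is uncertain, since a miR-1 precursor was listed on both strands in the 6-week pools. MiR-101b had 2 reads in WT replicate 1, was not listed in WT replicate 2, and had from 2 to 25 in KO. The edgeR adjusted p was 0.658 for each of these 10 microRNAs.

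In the deposited coordinates, whose build was not stated, miR-137-3p lay on chromosome 3 from 118136813 to 118136843, in the long noncoding gene Gm26871 of GENCODE vM21. MiR-132-5p lay on chromosome 11 from 74987189 to 74987216, in an intron of the noncoding 1700016P03Rik. MiR-140-5p lay on chromosome 8 from 110075149 to 110075174, within Wwp2, a ubiquitin ligase gene. MiR-326 lay on chromosome 7 from 106700839 to 106700863, in an intron of Arrb1, the beta-arrestin 1 gene. MiR-874-3p lay on chromosome 13 from 58124495 to 58124518, in an intron of Klhl3. MiR-101b lay on chromosome 19 from 29209829 to 29209855, in an intron of Rcl1.

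The microRNAs named in advance from work on Mecp2 and Bdnf did not pass either. MiR-30a-5p had a log2 fold change of 0.02 (SE 0.29), miR-381-3p one of −0.56 (SE 0.51) and miR-495-3p one of 0.84 (SE 0.63). MiR-132-3p had 0.25 (SE 0.57), miR-212-3p 0.36 (SE 0.67) and miR-199a-5p 1.12 (SE 0.70). Other arms of these precursors had the opposite sign, with miR-381-5p at 0.49, miR-495-5p at −0.19, miR-212-5p at −0.66 and miR-132-5p at −1.35. MiR-30a-3p (0.18) and miR-199a/miR-199b-3p (0.63) had the same sign as the arms above. Without WT replicate 2, miR-132-3p had −0.31, miR-212-3p −0.21 and miR-381-3p 0.44, and without WT replicate 1 miR-30a-5p had −0.18. MiR-495-3p had 0.05 without WT replicate 2 and 2.59 without WT replicate 1; miR-132-3p was also just under 0 without KO replicate 1. MiR-184, miR-134 and miR-146a were not among the tested features. Of the abundant microRNAs, miR-138-5p, which is enriched in neurons, had −0.62 (SE 0.31), and all 4 KO libraries were lower with TMM scaling but not with total counts or DESeq2 size factors. Another miR-138-5p feature had −0.63, with all 4 KO libraries lower with TMM and DESeq2 size factors but not with total counts. MiR-103-3p had 1.33 (SE 0.60), miR-29b-3p 0.05 (SE 0.28), miR-181a-5p 0.01 (SE 0.27) and miR-451 −0.30 (SE 1.12). Without WT replicate 2 these were 0.69, −0.13, −0.19 and 2.29, and without WT replicate 1 miR-103-3p had 2.45. Of the 90 8-week microRNAs that the naming rule covers, 69 had a log2 fold change that moved by over 1.5 times without 1 of the WT libraries, and in 34 of these it changed sign.

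Of 330 microRNAs tested, edgeR called 0, with a smallest adjusted p of 0.658, and 22 had an unadjusted p under 0.05 (6 higher and 16 lower, where 16.5 would be reached by chance). DESeq2 called 0 with 26 at an unadjusted p under 0.05, and limma-voom called 0 with 17. All 4 KO libraries were above both WT libraries for 16 microRNAs and below them for 30, which is 13.9%, where chance gives 13.3%; the counts were 15 and 16 with total-count scaling and 16 and 25 with DESeq2 size factors. Without WT replicate 1, edgeR called 3 microRNAs, miR-543-3p, miR-99a-5p and the miR-9-3p locus on chromosome 7 (smallest adjusted p = 0.0322), against WT replicate 2 alone, which is then assumed to vary like the KO libraries. Under the same assumption and with 1 residual degree of freedom, edgeR called 50 microRNAs in litter 2 alone and 1 in litter 1 alone, miR-129-3p (log2 fold change 2.13, adjusted p = 0.00248, both KO libraries higher). Those of litter 2 included miR-874-3p, miR-495-3p, miR-103-3p, miR-132-5p, miR-365, miR-326, the miR-9-3p locus on chromosome 7, miR-543-3p and miR-99a-5p. MiR-129-3p was also among them, in the direction opposite to litter 1 (log2 fold change −1.64). The standard error of a log2 fold change had a median of 0.46.

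**Figure D1:**
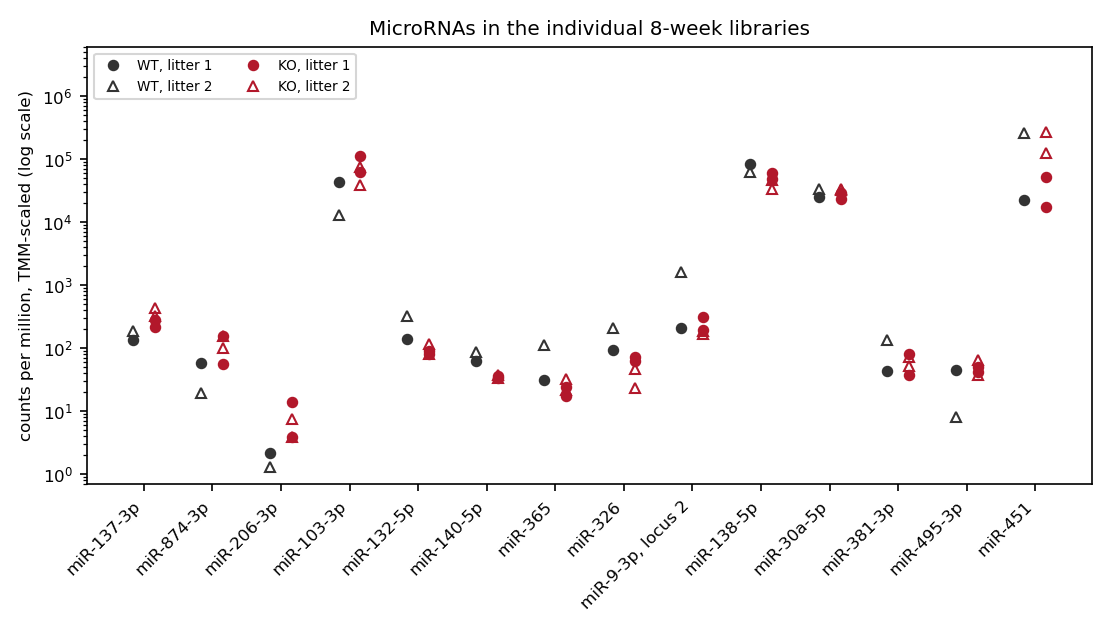
CPM (TMM-scaled, log axis) of 14 microRNAs in each 8-week library; points are single animals, black for WT and red for KO, filled circles for litter 1 and open triangles for litter 2. The 4 KO points of miR-140-5p lie close together (35.5 ± 1.64) below both WT points, while miR-451 spreads over both genotypes.

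The imprinted miR-379/miR-410 cluster of the Dlk1-Dio3 domain on chromosome 12, on which the study reported from these samples, showed no set difference at 8 weeks. Its 40 tested members had a median log2 fold change of 0.04, with 22 higher and 18 lower (limma camera adjusted p = 0.901; adjusted p = 0.910 with an estimated correlation). MiR-541-5p had −0.03 (SE 0.36), miR-487b-3p −0.16 (SE 0.27), miR-666-3p 0.07 (SE 0.45) and miR-543-3p 1.04 (SE 0.79). The median was −0.17 in litter 2 and without WT replicate 1, −0.04 without KO replicate 1, −0.02 without KO replicate 2, and above 0 without any other replicate. The neighbouring Gtl2/anti-Rtl1 microRNAs had 13 of 17 members higher and a median of 0.17 (camera adjusted p = 0.472), with miR-127-5p at 0.95 (SE 0.48) and miR-136-5p at −0.37 (SE 0.34).

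None of the other lists passed. The Bdnf 3'UTR list, part of which the study chose on these samples, so that it is not independent evidence, had 6 of 9 members higher, a median of 0.18 and a camera adjusted p of 0.472 (0.773 with an estimated correlation). The microRNAs tied to Mecp2 had 5 of 7 higher (median 0.36, camera adjusted p = 0.649) and the activity-regulated ones 6 of 10 (median 0.06, adjusted p = 0.472). Neuron-enriched microRNAs had 10 of 26 higher (median −0.07), with miR-124-3p at −0.17 (SE 0.51). The granule-neuron list had 8 of 15 higher (median 0.01), with miR-195-5p at −0.09 (SE 0.37). Both had a camera adjusted p of 0.472.

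Among the glial and vascular lists, the oligodendrocyte list had a median of 0.10 (miR-338-3p at 0.10, SE 0.35; miR-219-3p at −0.82, SE 0.83). The astrocyte list had −0.33, the microglia and white blood cell list −0.04 (miR-342-3p at −0.38, SE 0.33), the endothelial list −0.01, the smooth muscle list −0.33 and the choroid plexus list 0.65 (miR-204 at −0.07, SE 0.26; miR-34c-5p at 1.90, SE 0.92). The astrocyte and smooth muscle medians are both the value of miR-145-5p (SE 0.32), a smooth muscle and pericyte microRNA on both lists. The red blood cell list, which held miR-16 from separate loci (0.98 and 0.81), had a median of 0.81, with miR-144 at 1.36 (SE 0.87). The camera adjusted p was 0.472 for the astrocyte and choroid plexus lists, 0.5005 for the red blood cell list, 0.525 for the smooth muscle list, 0.963 for the oligodendrocyte and microglia lists and 0.987 for the endothelial list. The oligodendrocyte, microglia, endothelial, activity-regulated and X-linked lists had medians, means and test directions that differed in sign.

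Among the families, the miR-181 family had 6 of 7 members higher (median 0.33), with miR-181b at 0.67 (SE 0.31). Members are features, so loci of the same microRNA can enter separately. The miR-181 family also held miR-181b-5p (0.61). The let-7 family held several let-7a features (0.23, 0.19 and 0.19) and let-7f features (−0.45 and −0.76). The let-7 family had 12 of 17 lower (median −0.09), the miR-183/miR-96/miR-182 cluster 3 of 3 lower (median −0.42), the miR-30 family 5 of 7 higher (0.09) and the miR-29 family 5 of 7 higher (0.13). The miR-17/92 and paralog clusters had 11 of 14 lower (−0.17), the miR-15/miR-16/miR-195/miR-497 family 6 of 10 higher (0.71), the miR-34/miR-449 family 3 of 5 higher (0.72) and X-linked microRNAs 17 of 29 lower (−0.07). The camera adjusted p was 0.649 for the miR-17/92 clusters, 0.963 for X-linked microRNAs and 0.472 for each of the other families. Camera called 0 of 23 lists, with a smallest adjusted p of 0.472 and 1 list at an unadjusted p under 0.05. With an estimated correlation it called 0 (smallest adjusted p = 0.773) and fry called 0 in either mode (0.122 and, for changes in both directions, 0.669). No microRNA passed in edgeR when adjusted over the list alone, in any of the 23 lists. The medians of litter 1 and litter 2 had opposite signs in 10 of the 23 lists, among them the let-7 family (0.22 and −0.71), the miR-181 family (−0.12 and 0.61), the miR-29 family (−0.17 and 0.54), the miR-17/92 clusters (0.33 and −0.54), X-linked microRNAs (0.17 and −0.23) and the oligodendrocyte list (−0.21 and 0.33). The Hox-cluster list had too few tested members.

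Levels were also compared between litters. MiR-451 had a log2 difference of 2.84 between litter 2 and litter 1 that did not pass (edgeR adjusted p = 0.243), at 12.3% to 23.6% of the counts in litter 2 and 1.94% to 5.92% in litter 1. With genotype in the model, edgeR called 0 microRNAs between litters with 37 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 10. Without WT replicate 1 edgeR called 21, without WT replicate 2 it called 19, and without a low-count filter it called 1. Fold changes between KO and WT in litter 1 and litter 2 had a Pearson correlation of 0.02 across microRNAs, which are not independent replicates, and 174 of 330 had the same sign.

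The KO effect differed between litters for 15 microRNAs (edgeR interaction, adjusted p under 0.05), with 12 lower and 3 higher in litter 2. The lower ones included miR-25 and miR-93-5p, which share a primary transcript in Mcm7, the muscle-enriched miR-133a-3p and miR-133b, the miR-129-3p of chromosome 2, and miR-129-5p. MiR-129-3p had 1040 reads in WT and 3696 and 8716 in KO in litter 1, and 1447 in WT and 415 and 595 in KO in litter 2, a difference in log2 fold change of −3.90 (adjusted p = 0.0122). MiR-133a-3p had 18 reads in WT and 60 and 55 in KO in litter 1, and 41 in WT and 5 and 8 in KO in litter 2 (−4.13, edgeR adjusted p = 0.0122). The higher ones were miR-149-5p, miR-7a-3p and miR-543-3p. MiR-543-3p had 72 reads in WT replicate 2 and from 799 to 1428 in the other libraries (3.65, adjusted p = 0.0122). WT replicate 2 stood apart from the rest, with a mean correlation of 0.932 with the other libraries, where they had 0.955 to 0.967.

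The interaction rested on 1 WT library per litter and 2 residual degrees of freedom. DESeq2 called 20 and limma-voom 17, total-count scaling gave 7, a mean of at least 100 reads 6, and no low-count filter 32. Thinning every library to the smallest gave from 0 to 14 over 10 draws, and leaving out 1 KO library at a time gave 25 without replicate 2, 33 without replicate 1, 39 without replicate 4 and 47 without replicate 3.

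In the 6-week pools, 73 of 250 microRNAs were at least 1.5-fold apart with an interval excluding 1, 46 higher and 27 lower in KO. Highest were miR-190-5p, miR-340-5p, miR-137, miR-328, miR-1839-5p, miR-29a-5p, miR-125b-3p and miR-26b-5p. MiR-190-5p had 16 reads in WT and 87 in KO, a KO/WT ratio of 5.03 (95% interval 2.93 to 9.19). MiR-340-5p, in an intron of Rnf130, had a ratio of 3.27 (2.59 to 4.18), miR-137 one of 2.92 (2.19 to 3.93) and miR-328 one of 2.76 (2.44 to 3.13). MiR-1839-5p had 2.62, miR-29a-5p 2.37, miR-125b-3p 2.30 and miR-26b-5p, in an intron of Ctdsp1, 2.23. These comparisons are between the libraries, with no replicate check.

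Lowest were miR-222, miR-302a-3p, miR-16-5p, miR-302d, miR-22-5p, miR-652-3p, miR-221-3p and miR-302b. The X-linked neighbours miR-222 and miR-221-3p had ratios of 0.255 (0.215 to 0.300) and 0.405 (0.358 to 0.458). MiR-16-5p had 3454 reads in WT and 1362 in KO, a ratio of 0.365 (0.342 to 0.388). MiR-22-5p had 0.387 and miR-652-3p, in an intron of Tmem164, 0.394. The embryonic stem cell microRNAs miR-302a-3p, miR-302d and miR-302b had 0.285 (0.179 to 0.439), 0.381 (0.279 to 0.514) and 0.424 (0.302 to 0.588), and the 8-week libraries held at most 2 miR-302 reads.

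The activity-induced miR-132-3p had a ratio of 0.483 (0.442 to 0.528), miR-132-5p 0.630 (0.518 to 0.764) and miR-212-3p 0.536 (0.354 to 0.803). MiR-495 had 1.91 (1.70 to 2.14), miR-381-3p 1.59 (1.42 to 1.78) and miR-30a-5p 1.48 (1.41 to 1.55). MiR-206-3p had 1.55 (1.26 to 1.91), miR-134-5p 0.859 (0.651 to 1.13) and miR-199a-5p 0.690 (0.575 to 0.828). Among the most abundant, miR-29a-3p had 0.626 (0.620 to 0.632), miR-29c-3p 0.616 (0.610 to 0.622), miR-124-3p 1.64 (1.62 to 1.66), miR-103/miR-107-3p 0.896 (0.882 to 0.909) and miR-9-5p 1.10 (1.09 to 1.12). The median log2 ratio of all 250 was 0.08, and 0.17 with total-count scaling, a shift of 0.08. Of 89 microRNAs with at least 1000 reads, 20 were apart. The split was 57 higher and 21 lower with total-count scaling and 36 and 37 with DESeq2 size factors.

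**Figure D2:**
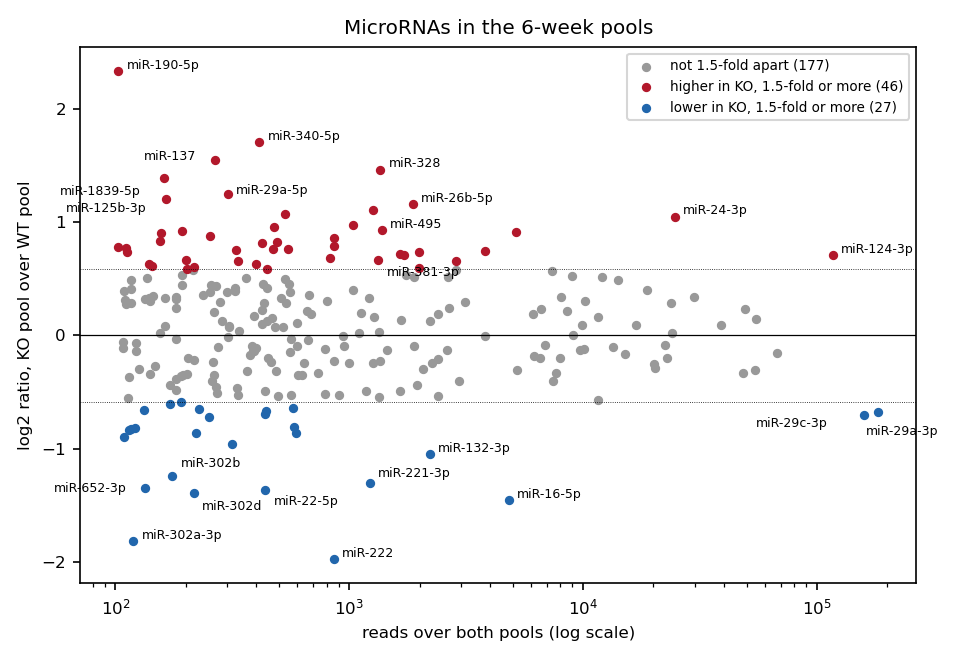
KO/WT log2 ratio of 250 microRNAs in the 6-week pools against their reads over both pools (log axis); each point is a microRNA, dotted lines mark 1.5-fold, and colours mark those counted as higher (46) or lower (27) in the KO pool. MiR-190-5p is highest at 2.33 and miR-222 lowest at −1.97.

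In the miR-379/miR-410 cluster, 25 of 33 members had a KO/WT ratio over 1 in the 6-week pools, with a median log2 ratio of 0.32. Of its members 7 were counted as apart, all higher, which is 21.2%, where 18.4% of all compared microRNAs were apart and higher. The median lay at percentile 94.3 of random lists. The study reported on this cluster from these samples, so that rank is not independent evidence. Random lists were drawn feature by feature, whereas the members are arms of 25 precursors of 1 cluster, so the percentile can overstate how unusual the median is. The median was 0.41 with total-count scaling and 0.24 with DESeq2 size factors. Its members miR-543-3p, miR-495, miR-666-3p and miR-381-3p had log2 ratios of 1.08, 0.93, 0.60 and 0.67, and miR-329-3p, from the same cluster, had −0.53. Counted as precursors, 20 of 25 lay above 1. The Gtl2/anti-Rtl1 microRNAs had a median of 0.25 (percentile 83.4), with miR-434-3p at 0.79 and miR-136-5p at −0.20.

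**Figure D3:**
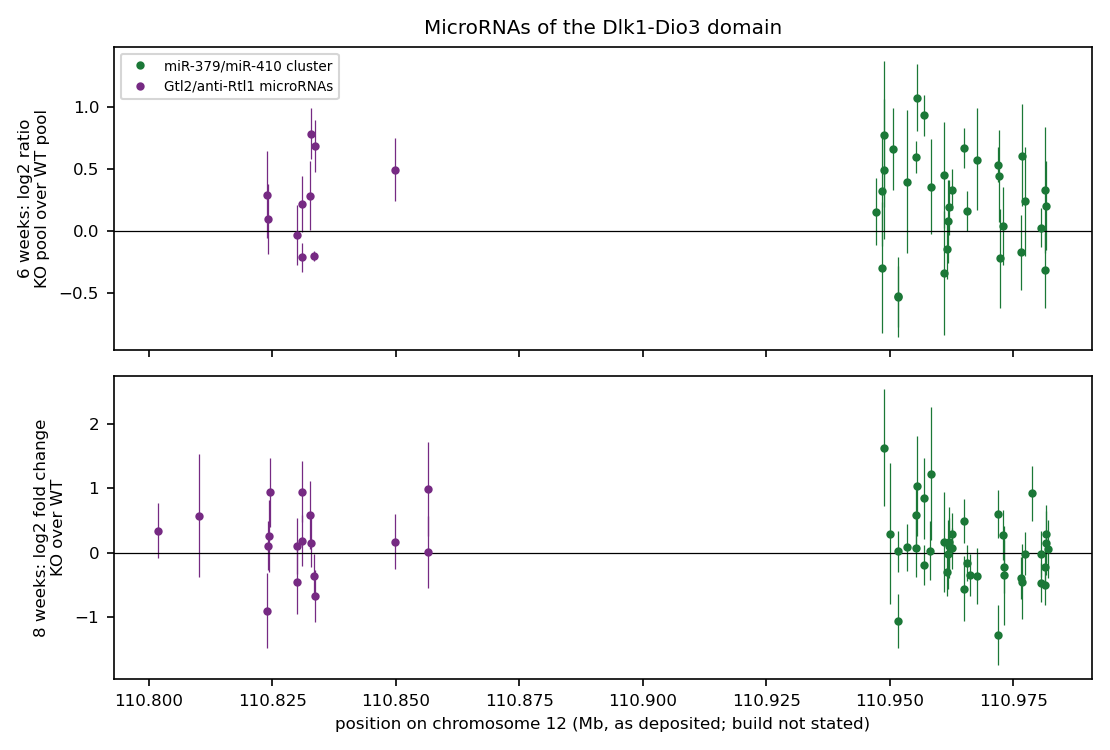
MicroRNAs of the Dlk1-Dio3 domain by deposited position on chromosome 12 (Mb, build not stated), green for the miR-379/miR-410 cluster and purple for the Gtl2/anti-Rtl1 microRNAs. The upper panel gives 6-week log2 ratios with 95% counting intervals (cluster median 0.32) and the lower panel 8-week log2 fold changes with standard errors (cluster median 0.04).

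The other lists at 6 weeks are described by their values, with no test, where the median log2 ratio of all 250 was 0.08. Random lists were drawn feature by feature, so percentiles can overstate how unusual a list with both arms of a precursor is. The list tied to Mecp2 held both arms of miR-132 and of miR-199a. The granule-neuron list held both arms of miR-9, miR-124 and miR-181a. The Bdnf 3'UTR list held both arms of miR-30a, and miR-381-3p and miR-495 from the same cluster. The red blood cell list held both arms of miR-486. The Bdnf 3'UTR list had 5 of 6 members above 1 (median 0.60, percentile 97.8), and the study chose some of its members on these samples. The granule-neuron list had 11 of 11 above 1 (median 0.42, percentile 95.4), with miR-497-5p at 0.74 and miR-9-3p at 0.71. Neuron-enriched microRNAs had 11 of 15 above 1 (median 0.14, percentile 64.8). The microRNAs tied to Mecp2 had 6 of 7 below 1 (median −0.53, percentile 1.92), with miR-137 as the exception. The red blood cell list had 5 of 5 below 1 (median −0.57, percentile 0.84), with miR-451 at a ratio of 0.675 (0.651 to 0.701). X-linked microRNAs had 11 of 16 above 1 (median 0.36, percentile 95.5) although miR-222, miR-221-3p and miR-652-3p were among the lowest ratios.

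The let-7 family had a median of 0.33 (percentile 91.6), the miR-181 family 0.31 (81.3) and the miR-15/miR-16/miR-195/miR-497 family 0.30 (77.4). The microglia list stood at 0.17 (55.4), with miR-150 at 0.86, and the miR-30 family at 0.09 (54.5). Below 0 were the astrocyte list at −0.15 (20.2), the smooth muscle list at −0.20 (18.4), the choroid plexus list at −0.10 (28.1), the miR-29 family at −0.11 (24.01), the miR-17/92 clusters at −0.26 (6.74) and the miR-34/miR-449 family at −0.19 (22.7). The activity-regulated (0.07, 49.8), oligodendrocyte (−0.08, 34.03) and endothelial lists (−0.06, 26.97) changed sign with the scaling. Medians and means differed in sign for the activity-regulated, endothelial, miR-29, miR-15/miR-16/miR-195/miR-497 and X-linked lists. The Hox-cluster and miR-183/miR-96/miR-182 lists had too few members here.

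Over pairs of features that overlapped in position, the 6-week log2 ratios and 8-week log2 fold changes did not go together (Pearson −0.02, Spearman −0.01; microRNAs are not independent replicates). The 8-week fold changes of litter 1 and litter 2 did not go together either (Pearson 0.02, the same sign in 174 of 330). Extraction, library kit and pooling also changed with age. The low correlation therefore cannot show whether KO effects differ between ages. In these pairs 12 of the 6-week microRNAs entered more than once, among them let-7a-5p, miR-16-5p and miR-9-3p, and the 8-week let-7b-3p was set against a 6-week let-7b-5p region that overlaps it. With each 6-week microRNA entered once, against its most-read 8-week partner and without that let-7b pair, the Pearson correlation over 210 microRNAs was 0.01 and 110, or 52.4%, had the same sign, where the shares of each sign alone give 49.6%. Of 18 pairs with an unadjusted edgeR p under 0.05 at 8 weeks, 9 had the same sign. Among those with the same sign, miR-137 had log2 values of 1.55 at 6 weeks and 0.95 at 8 weeks, and miR-140-5p −0.86 and −1.05. Among those with opposite signs, miR-326 had 0.82 and −1.55, and miR-331-3p 0.76 and −1.99. Of 60 microRNAs counted as apart at 6 weeks, each entered once, 33 had the same sign at 8 weeks (21 of 41 higher and 12 of 19 lower). Leaving out WT replicate 1 or KO replicate 4 gave a Pearson correlation of 0.03 and 0.02, and microRNAs with at least 1000 reads in the pools gave −0.21.

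**Figure D4:**
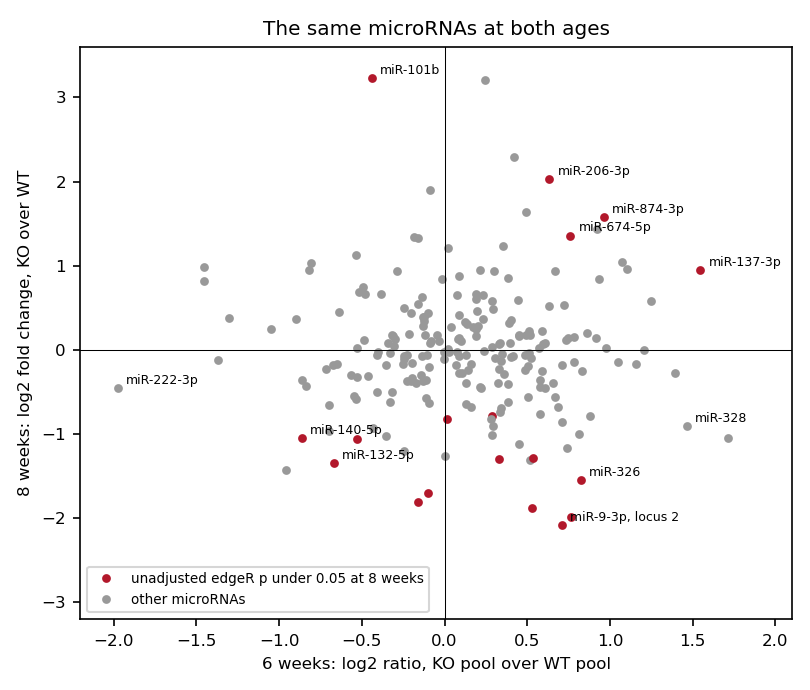
The 8-week log2 fold change against the 6-week log2 ratio for pairs of features that overlapped in position, each point a pair, in red those with an unadjusted edgeR p under 0.05 at 8 weeks. The points show no common slope (Pearson −0.02); miR-137-3p lies at 1.55 and 0.95, miR-326 at 0.82 and −1.55.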

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

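The tests of miR-302 and miR-451 below, and the count that compares litters as an explanation, were chosen after those results were seen; the tests of depth and of blood in WT replicate 2 were set before their results.

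The effect of the KO genotype differed between litters for 15 microRNAs by the edgeR interaction test. The log2 fold change was lower in litter 2 by −3.79 for miR-100-5p, −3.90 for miR-129-3p, −3.73 for miR-129-5p, −4.13 for miR-133a-3p, −3.66 for miR-133b, −4.40 for miR-25, −5.19 for miR-31, −2.77 for miR-497-5p, −3.43 for miR-872-5p, −3.28 for miR-93-5p and −3.48 for the miR-9-3p locus on chromosome 7. MiR-1944-5p, at −8.75 by the fit, was not listed in the KO libraries of litter 2, so this value is no measure of its size; it had 72 reads in their WT littermate and 59 to 83 in litter 1. The difference was 3.06 for miR-149-5p, 2.92 for miR-7a-3p and 3.65 for miR-543-3p.

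How much of this pattern lies in WT replicate 2 was not measured. WT replicate 2 had the lowest mean correlation with the other libraries over all microRNAs, 0.932. Lower depth was argued against, since it had the lowest mean correlation in 10 of 10 draws with every library thinned to 1494063 counts. Without the red blood cell list the mean correlation of WT replicate 2 was 0.933, still the lowest, where the next lowest had 0.956. Those microRNAs alone therefore do not account for it. The test cannot exclude blood, since a list with 5 of the 330 tested features can hardly move the correlation. KO replicate 4, with 22.7% miR-451, had 0.955 over all microRNAs, the lowest after WT replicate 2. A KO effect that differs between litters (15 microRNAs) and a deviation of that single library cannot be told apart, because each litter had 1 WT animal.

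MiR-302 microRNAs, known from embryonic stem cells, were listed in both 6-week pools with 403 reads in WT and 156 in KO, whereas 1 of the 8-week libraries had 2 reads. A candidate explanation is RNA or reads from another source in the multiplexed pools: its prediction of 1 common KO/WT ratio over the 5 miR-302 regions was met (chi-square test with 100000 Monte Carlo draws, p = 0.367), but these microRNAs share a transcript, so a genotype effect would give the same. Mouse embryonic stem cells as that source were argued against, since the miR-290 to miR-295 group, abundant in them, had 0.0304 times the reads of miR-302 (17 against 559). Lower miR-302 expression without Mecp2 cannot be told apart from these, with 1 pool per genotype and at most 2 reads in an 8-week library.

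MiR-451 ranged from 1.94% to 23.6% of the 8-week counts and was higher in every library of litter 2 than in litter 1. Blood left in the tissue may account for this, and would raise other red blood cell microRNAs with it. MiR-144, from the same cluster, had a Pearson correlation of 0.783 with miR-451 over 6 libraries (exact permutation p = 0.0514, adjusted over 6 relations p = 0.154) and a Spearman correlation of 0.886 (exact permutation p = 0.0333, adjusted p = 0.1), and r = 0.643 without the 2 libraries farthest from the median. MiR-15b and miR-223-3p went the same way without passing (Pearson 0.665 and 0.431, exact permutation p = 0.182 and 0.407; 0.847 and 0.625 without the 2 farthest). MiR-16 did not follow in either of its features (Pearson −0.12 and −0.23, exact permutation p = 0.800 and 0.651), and miR-150, a lymphocyte microRNA, went the other way (Pearson −0.98, exact permutation p = 0.00417, adjusted p = 0.025; Spearman −0.94, exact permutation p = 0.0167, adjusted p = 0.1; Pearson −0.94 without the 2 farthest). The libraries fell into 2 litters of 3, too few for a value within litters, so blood and another difference between litters cannot be told apart.

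MiR-30d-5p stood at 6913 CPM in KO replicate 3, set apart from the other 3 KO libraries by Dixon's criterion. The criterion compares a gap with the range of the KO values, not with a fixed size. The log2 fold change was −0.093 with that library and −0.094 without it. Chance alone gives such a gap in about 1 in 20 microRNAs, and of the 90 examined only miR-30d-5p had it. MiR-326 and miR-328 had 6-week log2 ratios of 0.82 and 1.46, whereas all 4 of the 8-week KO libraries lay below both WT libraries (for miR-328 with TMM and DESeq2 size factors, not with total counts); this difference between ages was not tested.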

How the results depend on the processing

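All alternatives were planned except the uncollapsed regions, the removal of blood microRNAs, 1 arm per precursor, each 6-week microRNA once, tests of single litters, the values of the 5 most abundant microRNAs and of list members, thinning, and the interaction without each KO replicate, which were chosen after seeing the data. For the values that moved or reversed, the cause was not tested except where stated. The 0 calls at 8 weeks held under both other scalings, both other count filters, DESeq2, limma-voom, uncollapsed regions and without blood microRNAs (smallest adjusted p from 0.370 to 0.839), and ranged from 0 to 3 without 1 replicate, with 3 only without WT replicate 1. In litter 1 alone edgeR called 1 and in litter 2 alone 50, each against 1 WT library. With litter as a replicate block, edgeR called 0 (27 at an unadjusted p under 0.05) and the cluster median was 0.01; the paired fit changed no call. The list calls stayed at 0 in every setting run. The 8-week cluster median ranged from −0.17 to 0.16 without 1 replicate and was −0.17 in litter 2 alone. Without 1 replicate, named microRNAs that reversed ranged from −0.18 to 0.20 (miR-30a-5p), −0.31 to 1.16 (miR-132-3p, with −0.00155 without KO replicate 1), −0.21 to 1.38 (miR-212-3p), −1.17 to 0.44 (miR-381-3p), −2.92 to 0.0144 (miR-9-3p of chromosome 7), −0.130 to 0.198 (miR-29b-3p), −0.185 to 0.195 (miR-181a-5p) and −1.20 to 2.29 (miR-451, with 0.0491 without KO replicate 1), each range between the fits without WT replicate 1 and without WT replicate 2. MiR-451 had 0.0663 with litter as a block. In litter 1 alone these reversed: miR-9-3p of chromosome 7 (0.253), miR-29b-3p (−0.390), miR-181a-5p (−0.248), miR-451 (0.562), miR-212-5p (0.327), miR-381-3p (0.399) and miR-495-3p (−0.00340). Of 396 values of 26 named 8-week microRNAs under the alternatives, 370 kept their direction and their side of the threshold, 18 reversed and 8 passed, the −2.92 of miR-9-3p without WT replicate 1 and 7 in litter 2 alone.

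The interaction count was 7 with total counts, 32 without a filter, 6 at a mean of 100 reads, 25 to 47 without 1 KO replicate, and 0 to 14 over 10 thinning draws (median 11.5). The litter count was 1 without a filter, 10 by DESeq2 and 0 to 21 without 1 replicate. At 6 weeks, 20 of 89 microRNAs with 1000 reads were apart (fewer compared), and the cluster median was 0.41 with total counts, 0.24 with DESeq2 size factors and 0.44 over 7 members at 1000 reads. The correlation between ages was −0.207 at 1000 reads, −0.0481 without the cluster, −0.0397 to 0.0272 without 1 replicate and 0.0149 with each 6-week microRNA once. None of the 16 microRNAs named for the highest and lowest 6-week ratios changed side in 52 comparisons; miR-7a-5p, at 0.970, had 1.03 with total counts. Passenger strands are not marked in the files, so leaving them out was not run. Depth limits microRNAs such as miR-1-5p, miR-101b and miR-206-3p, with at most 33 reads in a library.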

Other observations

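The tests on both arms of a precursor were set before their results, except that reading them by the bootstrap interval was chosen after; the splits of the samples were examined after the correlation was seen.

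Of 50 precursors with both arms compared in the 6-week pools, 30 had log2 ratios of opposite sign, 2 had arms counted as apart in opposite directions and 3 in the same direction. MiR-29a-5p had a KO/WT ratio of 2.37 and miR-29a-3p one of 0.626, and miR-140-3p had 1.68 and miR-140-5p 0.549. MiR-126-5p, from a vessel-specific precursor, had 1.88 and miR-126-3p 0.755. MiR-7a-3p had 2.15 and miR-7a-5p 0.970, or 1.03 with total counts. MiR-132-5p and miR-132-3p, at 0.630 and 0.483, were both below 1.

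If ratios were set at the precursor, for example by transcription, both arms would carry them. The hypothesis was tested by the spread over precursors of the 5p minus 3p log2 ratio. Its SD was 0.88 (95% bootstrap interval 0.70 to 1.03 over 50 precursors), where counting error alone would give 0.22 and shuffled pairs gave a median of 0.81 (permutation test with 100000 shuffles, one-sided p = 0.918). A ratio set wholly at the precursor would leave the 0.22 of counting error, and the whole interval lies above it. These values argue against the precursor as the only source of the 6-week ratios. By the rule set before the result the explanation failed, since the spread was not under the shuffled median. The interval includes that median, so a part set at the precursor stays open. A difference between libraries in how arms were captured and a difference in processing or decay stay open as well. At 8 weeks the SD was 0.98 (95% bootstrap interval 0.82 to 1.14 over 89 precursors) against 1.02 for shuffled pairs (one-sided permutation p = 0.245), which leaves a part set at the precursor undecided there. Pearson correlations between arms were −0.20 at 6 weeks and 0.07 at 8 weeks, across precursors.

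The hypothesis that the KO effects of both ages are shared was examined by other splits of the 8-week libraries into 2 and 4. The real split gave a Pearson correlation with the 6-week ratios of 0.02 on the log CPM scale, and the highest of the others 0.117; 6 of the 15 splits, the real one included, gave one as large. With 15 splits the share cannot be under 0.05.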
